A study of Mus musculus with 4 samples.

How the data were processed

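The deposited scanner signals are an intensity, which the authors obtained with Agilent Feature Extraction 11.5.1.1, with background subtracted and spatial trends removed within each array and no scaling between arrays, per the file headers. The series value table is a ratio that the authors made by dividing each deposited signal by its array's 75th percentile on a linear scale. Over 44397 spots it differed from that quotient by at most 2.3e-07 in relative terms. The medians of that table were 0.066, 0.0623, 0.0612 and 0.0645 in +/+ cells without and with calcium and −/− cells without and with calcium. For each array 200 ng of RNA was labelled, per the labels.

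The analysis started from the scanner signals. Spots marked as outliers by the scanner software (107, 112, 105 and 116 on the arrays in the same order) were dropped and no spot was saturated. The signal was taken as log2 and the array's 75th percentile over 43020 non-control spots was subtracted. Those percentiles were 2638, 2737, 2889 and 3300 intensity units, and 67.0%, 67.0%, 67.3% and 68.6% of 39426 probes were well above background. The median SD of log2 signal over the 10 spots of a repeated probe was 0.06 on each array. Probe positions are those of mm9 as given in the files. Of 39429 probes 27508 were named through their transcript accession and 11921 kept the name in the file. They stand for 30340 genes or targets, 7144 of them with more than 1 probe, and each gene was read from its brightest probe. Among genes at least 2-fold different by that probe and with further measured probes, the probes had opposite signs for 8 of 94 in the +/+ calcium response, 5 of 67 in the −/− response, 29 of 222 without calcium and 44 of 337 with calcium.

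A gene was compared where it was well above background on at least 1 of the 2 arrays. Where the other array was dim, the difference was computed against a limit and given as a lower bound ("at least"). The limit was the higher of the gene's own value there and the lowest probe signal well above background on that array. Where the gene's own value was the higher, the bound equals the measured difference. The difference of the calcium responses was computed only for genes well above background on all 4 arrays. Genes were counted at 2-fold, and no test was run since each group is 1 array. The genes named were members of the lists, plus, per comparison and direction, the 10 largest differences among genes measured on both arrays, whose measured probes all went the same way and whose symbol is no clone or model name, and the 3 largest bounds among such genes. A condition was added to this rule: a gene with a bound was not named where another of its probes was well above background on the dim array, which applied to 17, 14, 19 and 21 genes in the calcium responses of +/+ and −/− cells and the genotype differences without and with calcium. These genes still count in the totals, where their bound depends on the probe chosen. A few genes that this rule names are left out of the text. The gene Pla2g2f and its 5 Mb surroundings were also examined.

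There were 40 gene lists, 25 of functions and 15 of cell type markers, with 855 entries, of which 10 were not found on the array. The median of a list was set against 10000 random lists matched on mean level in 20 bins, and a list stood apart when outside their central 95%. The lists, the rules for naming genes and most alternatives were chosen before the data were examined.

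The steps were tested on arrays simulated from each gene's mean level and the spread between repeat spots. They hold technical noise within an array and no spread between cultures, so recovery tests the code and says nothing about replicates. All 100 genes given a 4-fold and all 100 given a 2.5-fold difference were recovered past 2-fold, and 0 of 21146 unchanged genes were called. For bounds, measured values of 19227 genes well above background on all 4 arrays were used, with the untreated +/+ array treated as dim. By construction the bound there equals the measured difference, or 0 where that was negative. That 0 bounds exceeded it tests the code only and covers no truly dim gene. In the measured genotype difference without calcium, of 2000 random lists of 20 genes 94.05% fell inside the central range, and of 2000 lists raised by 0.5 log2 99.9% were found. The number of simulated lists was enlarged to 2000 after a smaller run had given a lower share inside the range.

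Alternatives were normexp background correction with an offset of 50, quantile scaling, scaling to the median of probes well above background, the mean of a gene's probes, the authors' value table, genes well above background on both arrays, no filter, a 3-fold threshold, and list medians without bounds or with near-identical families counted once. Scaling to basal keratinocyte genes was added after the data were seen. The software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.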

Results

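Keratinocytes, the epithelial cells that build the epidermis, were freed from the skin of newborn mice with 0.05% collagenase, grown for 3 days and then held for 48 h in medium with or without 1 mM added CaCl2. Added calcium is the usual switch from growth to terminal differentiation in such cultures. Pla2g2f encodes a secreted phospholipase A2, an enzyme that splits a phospholipid into a fatty acid and a lysophospholipid, and the series asks how its loss affects the differentiation and activation of these cells. Cells labelled Pla2g2f +/+ and −/− were measured on 1-colour expression arrays, 1 array for each of the 4 combinations of genotype and calcium. Samples were pooled from keratinocytes of 6 mice per genotype, so genotype and cell preparation cannot be told apart. With 1 array per group no difference has a replicate check or a p-value, and the number of arrays limits the precision. Each array had 67.0% to 68.6% of its 39426 probes well above background, and 19227 genes were well above background on all 4 arrays.

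Pla2g2f was well above background on every array, and its level was lower in −/− than in +/+ cells by less than 2-fold. Its probe lies on chromosome 4 at 138306448 to 138306507 (mm9) and contains a canonical polyadenylation signal. The deleted part of the gene is not given in the labels, so a probe at this end of the transcript checks nothing about them. The level relative to the 75th percentile of the array was −3.35 and −3.04 log2 in +/+ cells without and with calcium, and −3.78 and −3.53 in −/− cells. The −/− signal stood at 74.2% of the +/+ signal without calcium (log2 difference −0.43, scanner error 0.23) and at 71.1% with calcium (−0.49, scanner error 0.22). The median gene was also lower in −/− cells, by −0.18 and −0.16, and relative to it the Pla2g2f difference was −0.25 and −0.33. Pla2g2f was 1.24-fold higher with calcium in +/+ cells and 1.19-fold higher in −/− cells.

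The calcium response of +/+ cells shows how cultures labelled wild type differentiate. Calcium-treated +/+ cells had far more transcript of cornified envelope genes, which build the tough shell of dead surface cells. They also had more of the proteases that shed that shell and of tight junction genes. Integrins, laminins and other genes of the basal layer, where dividing keratinocytes sit, were slightly lower, as were genes of DNA replication and mitosis. In all, 522 genes were at least 2-fold higher and 214 at least 2-fold lower of 21129 compared, with 118 and 86 of these counted from a lower bound.

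The late differentiation list had a median of 3.85 log2 (14.5-fold) in +/+ cells, with 39 of 48 measured genes at least 2-fold higher and 1 lower. Among its members, cornifelin (Cnfn; probe on chromosome 7 at 26152727 to 26152786, mm9) was 65.7-fold higher, Lce1f 36.4-fold, Lce3c 28.8-fold, Lce1d 28.7-fold and both Lce3a and Kprp 27.6-fold. The cross-linking enzyme Tgm1 was 20.5-fold higher and loricrin (Lor), the main envelope protein, 16.6-fold. Bounds were at least 30.8-fold for sciellin (Scel) and at least 29.2-fold for Lce3e, both not well above background without calcium. The same holds for the amino acid transporter Slc6a14, at least 28.5-fold higher. All 18 late cornified envelope (Lce) genes were at least 2-fold higher, with a median of 19.7-fold. The exception in the list was the deiminase Padi3, 2.08-fold lower.

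Other parts of the differentiation programme were higher in +/+ cells with calcium too. Early, spinous-layer genes had a median of 1.36 log2, with 10 of 19 at least 2-fold higher, among them Krtdap (22.9-fold), Hopx (12.2-fold) and Grhl3 (7.68-fold), a transcription factor of barrier formation. The desquamation list of proteases and inhibitors had a median of 1.34, with 14 of 19 genes at least 2-fold higher, led by the kallikreins Klk6 (35.9-fold) and Klk7 (29.3-fold) and the cathepsin inhibitor Cst6 (26.7-fold). Barrier lipid genes had a median of 0.68, with the ceramide hydroxylase Degs2 6.21-fold and the sulfotransferase Sult2b1 7.92-fold higher. The tight junction and desmosome list had a median of 0.80, including claudin 3 (Cldn3, 5.39-fold), occludin (Ocln, 4.17-fold) and the gap junction protein connexin 26 (Gjb2, 5.65-fold). In the activation and hyperplasia list the median was 0.55 and 13 of 37 genes were at least 2-fold higher, such as beta-defensin 14 (Defb14, 46.4-fold) and keratin 16 (Krt16, 7.57-fold). EGF receptor ligands and their feedback genes had a median of 0.51, with epiregulin (Ereg) 3.53-fold higher.

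Lower in calcium-treated +/+ cells were basal keratinocyte genes (median −0.32; 15 of 20 below 0), with Itga3, a laminin-binding integrin, 2.41-fold lower and Col17a1, a hemidesmosome collagen, 1.80-fold lower. Cell cycle genes had a median of −0.30, with 31 of 36 below 0 and none at 2-fold. The genes lower by the most were Lgr5, a Wnt pathway receptor of stem cells (5.02-fold), Serpinb10 (4.98-fold), Prl6a1 (4.5-fold), the glutathione transferase Gsta2 (3.65-fold), the natural killer receptor genes Klra12, Klra7 and Klra15, the chemokine Ccl3 (3.14-fold), Frem1 and Arsb. With normexp correction Klra12, Klra7, Ccl3, Frem1 and Arsb were less than 2-fold lower. The largest bounds on the low side were Olfr312 (at least 5.1-fold), Eif5b and Slc13a4 (each at least 4.93-fold). With normexp background correction the counts were 328 higher and 62 lower, and with every gene kept regardless of signal they were 886 and 1097. The share of higher genes among all 2-fold calls was 70.9%, against 84.1% with normexp correction and 91.2% when arrays were scaled to basal keratinocyte genes.

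The same treatment of −/− cells asks whether differentiation proceeds in cells labelled as lacking the gene. Here too calcium-treated cells had more transcript of early and late differentiation genes, shedding proteases, barrier lipid enzymes and tight junction genes. The largest difference among the genes named was in Aldh1a3, which makes retinoic acid. This gene was higher with calcium in +/+ cells too, with levels of −8.25 log2 without and −2.40 with calcium. Its untreated +/+ level lay under that array's limit of −6.07, so it could not enter the same ranking there. Cell cycle genes did not stand apart. At least 2-fold higher were 640 genes and lower 129 of 21428 compared, of which 205 and 70 were counted from a lower bound.

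In −/− cells the early list had a median of 1.74 log2 (12 of 19 genes at least 2-fold higher) and the late list 1.54 (38 of 48). The largest differences on the high side were Aldh1a3 (44.5-fold), Scel (39.2-fold), Defb14 (34.3-fold), Cnfn (31.0-fold), Pdzk1ip1 (25.6-fold), Ly6g6e, Cst6 (23.1-fold), the proton pump subunit Atp6v1c2, Klk6 (20.1-fold) and Krt90. The largest bounds were another proton pump subunit, Atp6v0a4 (at least 30.9-fold), Rhov and Mab21l4. Lce genes had a median of 2.73-fold, with 15 of 18 at least 2-fold higher. Desquamation genes had a median of 1.69, tight junction and desmosome genes 0.72, barrier lipid genes 0.76, activation genes 0.37 and EGF receptor ligands 0.33. In the early list the desmosomal cadherin Dsg1b was 18.2-fold higher, and at least 11.4-fold in +/+ cells.

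Basal keratinocyte genes had a median of −0.39 in −/− cells with calcium (17 of 20 below 0), Itga3 being 2.17-fold and Krt15, a basal keratin, 2.11-fold lower. Lower by the most were Ptgds, a prostaglandin D2 synthase (3.53-fold), Gsta2 (3.48-fold), Npr3, Serpinb10, Rnu3b1, Lgr5 (3.06-fold), Gpr143, the water and glycerol channel Aqp3, Krt20 and Gzmb. Bounds on the low side were led by Myh4, Slc25a2 and Alkbh3os1. With normexp correction Npr3, Krt20, Gzmb, Slc25a2 and Alkbh3os1 were less than 2-fold lower. Ribosomal protein genes had a median of −0.22 with all 29 below 0. Matched random lists were also below 0 (−0.21 to −0.14), so the ribosomal list lay only just outside their range. The counts were 319 higher and 26 lower with normexp correction, and 1919 and 447 with every gene kept regardless of signal. The share higher was 83.2%, against 96.8% with scaling to basal keratinocyte genes and 73.2% with quantile scaling.

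Set against each other, the calcium responses overlapped widely but differed in the cornified envelope cluster. Lce and Sprr2 genes, which encode small cross-linked envelope proteins, responded far less in −/− cells, while late genes of other families went both ways. Cell cycle genes lay on the other side by small amounts (median 0.29 log2), and most Langerhans and myeloid markers by more (median 0.88). Chemokine genes as a list of 12 measured genes lay lower in the −/− response, with 1 of them at least 2-fold above 0. The chemokines Ccl3, Ccl6 and Ccl9, not all of them members of that list, were lower with calcium in +/+ cells and higher in −/− cells.

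Among 19227 genes the responses correlated across genes with Pearson r = 0.618 and Spearman rho = 0.361, genes not being independent replicates. At least 2-fold higher in both were 248 genes, against 7.8 for independent lists, and 13 were lower in both, against 0.3. The SD of the response over genes was 0.44 log2 in +/+ and 0.38 in −/− cells. For the 390 genes at least 2-fold higher in +/+ cells the median was 1.51 in +/+ and 1.25 in −/− cells. For the 384 chosen in −/− cells it was 1.34 and 1.45, and for the 335 chosen on the mean of both genotypes it was 1.71 and 1.54. For the 119 genes at least 2-fold lower in +/+ cells the median size of the response in that direction was 1.17 in +/+ and 0.27 in −/− cells, and 113 were smaller in −/− cells. For the 46 at least 2-fold lower in −/− cells it was 0.71 in +/+ and 1.14 in −/− cells, and choosing genes in 1 genotype favours that genotype.

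**Figure D1:**
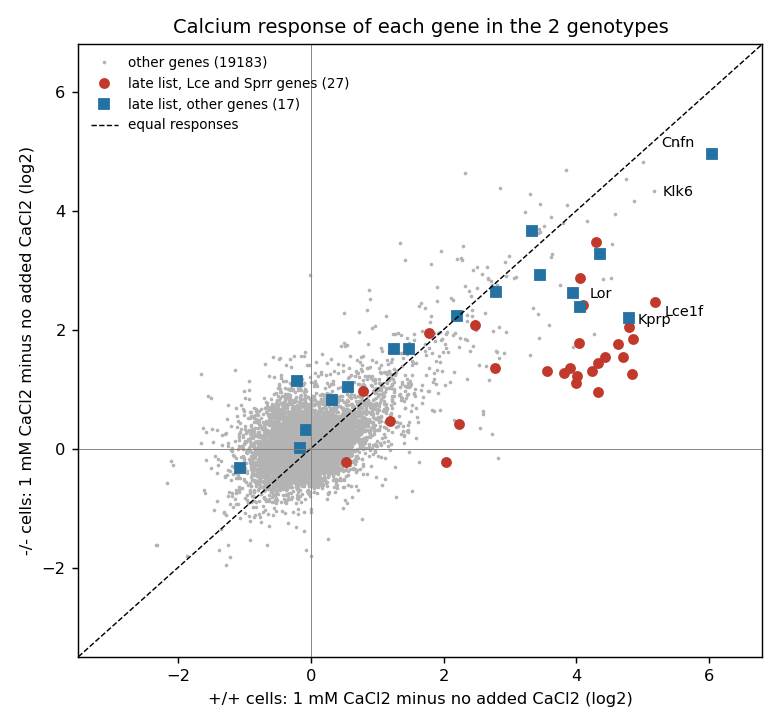
Calcium response of each of 19227 genes (log2, 1 mM CaCl2 minus no added CaCl2) in +/+ cells on the horizontal axis and −/− cells on the vertical axis, 1 array per group; the dashed line marks equal responses. Of the 27 Lce and Sprr genes of the late list, 25 lie below the line, as do 7 of the 17 other late genes.

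The signed response difference, −/− minus +/+, was at least 2-fold above 0 for 367 genes and at least 2-fold below 0 for 121. A positive value does not mean a stronger response, since it also arises where a gene was lower with calcium in +/+ cells only. Quantile scaling turned this into 187 and 184, so the share above 0 was 75.2% with the 75th percentile, 50.4% with quantiles and 63.2% with normexp correction. The late list had a median response difference of −1.38, with 26 of 44 genes at least 2-fold below 0. Split by family, 17 Lce genes had a median of −2.74 (6.68-fold smaller) and 7 Sprr2 genes −2.26, and these signs were the same under each of the 7 settings of scaling, background and probes. The other 17 late genes without Lce or Sprr went both ways around a median of 0.17. Of these, 5 were at least 2-fold smaller, namely Kprp (6.03-fold), Lor (3.21-fold), the protease Asprv1 (2.53-fold), Cnfn and Tgm1 (each 2.12-fold), and Padi4 had a difference of 2.55-fold above 0. Sprr1 genes had a median of −0.79. The 10 genes with the lowest response difference were Lce1d (12.1-fold; chromosome 3, 92489446 to 92489505, mm9), Lce1e (10.3-fold), Lce1a1 (8.9-fold), Lce3c (8.02-fold), the niacin receptor Hcar2 (7.88-fold), Lce1b, Sprr2e (7.44-fold), Lce3d, Sprr2g and Lce3b.

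The response difference was highest for the regenerating lectins Reg1 (7.57-fold) and Reg3g, the chemokines Ccl3 (7.47-fold), Ccl6 and Ccl9, the scavenger receptor Marco, Psg19, Ly6g6e, Depp1 and Camkv. Of these, Ly6g6e and Depp1 were higher with calcium in both genotypes, and the others were higher in −/− cells and at or below their untreated level in +/+ cells. Cell cycle genes had a median of 0.29, with 32 of 34 above 0, among them Ccna2 (2.14-fold) and Mki67 (1.77-fold). Myeloid markers had a median of 0.88 with 10 of 13 above 0 and fibroblast markers 0.40 with 18 of 19 above 0. Adipocyte (0.35), mast cell (0.37) and sebaceous (0.39) markers also stood apart on this side, and melanocyte markers (−0.27) and hair follicle markers (−0.10) on the other. Chemokines had a median of −0.29, with Cxcl1 2.01-fold and Cxcl5 2.10-fold below 0. Immediate early (−0.24), desquamation (−0.23), heat shock (−0.19), p53 target (−0.18) and interferon (−0.07) genes were lower, and hypoxia and glycolysis (0.19), eicosanoid (0.17), fatty acid and PPAR (0.16), NRF2 target (0.12) and TGF-beta (0.09) genes higher, than matched random lists.

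Cells without added calcium show what the genotypes differ in before differentiation is induced. Most mast cell and adipocyte markers were several-fold higher in −/− cells, and so were 7 of 14 Langerhans and myeloid markers, at 2-fold or more. Fatty acid synthesis and PPAR target genes, eicosanoid genes and interferon genes were higher as lists, by less than 2-fold at the median. Keratinocyte activation genes, which mark wounded or inflamed epidermis, were lower, as were cell cycle, basal and tight junction genes by smaller amounts. At least 2-fold higher were 992 genes and lower 922 of 21346 compared, of which 162 and 397 were counted from a lower bound. The counts were 655 and 188 with normexp correction, and 1332 and 2982 with every gene kept regardless of signal.

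Without calcium the mast cell list had a median of 3.04 log2 (8.25-fold), with 9 of 9 genes at least 2-fold higher in −/− cells, led by the mast cell proteases Mcpt4 (25.5-fold; chromosome 14, 56678589 to 56678648, mm9), Cpa3 (16-fold) and Cma1 (14.5-fold). Adipocyte markers had a median of 2.48 (8 of 9), with adiponectin (Adipoq) 9.80-fold and adipsin (Cfd) 8.6-fold higher. Langerhans and myeloid markers had a median of 1.22 (7 of 14), with Adgre1 4.88-fold and Cd68 4.07-fold higher, while the class II gene H2-Ab1 was 1.64-fold lower. Fibroblast markers (median 0.77), erythroid (1.08; 3 of 6 above 0 and 3 below), Schwann cell (1.01), skeletal muscle (0.64), melanocyte (0.52), pericyte and smooth muscle (0.44) and sebaceous (0.40) markers were higher than matched random lists. Endothelial (−0.39), T cell (−0.31) and Merkel and simple epithelial (−0.03) markers did not stand apart, and hair follicle markers were lower (−0.48). X inactivation and Y-linked genes (0.10) did not stand apart in this or the other comparisons.

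The largest single differences on the high side without calcium were Cd5l, a macrophage protein (36.5-fold), Mcpt4, the cytochrome P450 Cyp2e1 (18.0-fold), Cpa3, Slco2b1 (14.7-fold), Cma1, carbonic anhydrase 3 (Car3, 12.9-fold), the gluconeogenic enzyme Pck1, Cox8b and Nell1. Bounds were led by Thrsp (at least 15.4-fold), Ces1f and Itih4. Fatty acid synthesis and PPAR target genes had a median of 0.89, with 11 of 29 at least 2-fold higher, including Cd36 (5.22-fold) and Pdk4 (4.83-fold), and 6 of the list's members stand in the adipocyte or sebaceous lists. Eicosanoid genes had a median of 0.34, with 10 of 27 at least 2-fold higher, such as Ephx2 (7.1-fold), Alox5ap (5.0-fold) and the prostaglandin receptor Ptger3 (4.76-fold). Interferon response genes had a median of 0.54 (24 of 27 above 0), with Ifi27l2a 5.56-fold higher. Oxidative stress genes of the NRF2 pathway had a median of 0.31, lysophospholipid genes 0.12 and unfolded protein response genes 0.13. In the lysophospholipid list Enpp2, the enzyme that makes lysophosphatidic acid, was 6.94-fold higher. These groups were higher in the same −/− libraries in which mast cell, adipocyte and myeloid markers had medians of 3.04, 2.48 and 1.22.

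Activation and hyperplasia genes had a median of −0.43 without calcium, with 9 of 34 genes at least 2-fold lower in −/− cells. Among them were the neutrophil growth factor Csf3 (6.58-fold), the antimicrobial S100a8 (5.38-fold), the alarmin Il33 (4.53-fold), Slpi (3.57-fold) and lipocalin 2 (Lcn2, 2.45-fold). Krt6a was 1.76-fold lower, and arginase (Arg1) was 2.63-fold higher against the direction of the list. The single genes lower by the most were the prolactin family genes Prl8a6 (9.61-fold), Prl8a9 and Prl6a1, the Golgi GTPase Rab6b (7.14-fold), Csf3, Bcl2l15, Wfdc2, Ell3, the pattern recognition protein Ptx3 (5.54-fold) and Sprr2j-ps, with Olfr312 and Npas1 among the largest bounds. Cell cycle genes had a median of −0.37, tight junction and desmosome genes −0.31, cholesterol synthesis genes −0.28 and basal keratinocyte genes −0.28, just outside the central 95% of random lists (−0.27 to −0.04). With quantile scaling (−0.17) or the mean of a gene's probes (−0.28) the basal list did not stand apart.

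Differentiation genes as lists did not differ much between genotypes without calcium. The early list had a median of −0.12 and the late list −0.05, both within the range of random lists. Quantile scaling turned the late median to 0.0795, above that range, and the late families differed from each other. Lce genes were higher in −/− cells (median 0.81; 6 of 18 at least 2-fold), with Lce1f 4.12-fold and Lce1a1 3.96-fold higher, and Sprr2 genes lower (−0.94; 3 of 7). Klk6 was 6.17-fold and Cst6 5.74-fold higher, and the desquamation list had a median of 0.07, above matched random lists. Other late genes had a median of −0.21, which turned to 0.08 when arrays were scaled to basal keratinocyte genes. The share of higher among all 2-fold calls was 51.8% with the 75th percentile, 77.7% with normexp correction and 74.4% with quantile scaling. It was 81.8% with scaling to basal keratinocyte genes and 30.9% with every gene kept regardless of signal. The balance of higher and lower genes is therefore not set by these data.

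With calcium the genotype comparison shows the differentiated state. Sprr2 and Lce genes, including those that had been higher in −/− cells before treatment, were now lower there, and activation genes as a list and the neutrophil-attracting chemokines Cxcl1 and Cxcl5 were lower too. Mast cell, adipocyte and fibroblast markers were higher for most genes of each list, and Langerhans and myeloid markers for 9 of 13. At least 2-fold higher were 1413 genes and lower 658 of 21564 compared, of which 257 and 140 were counted from a lower bound. The share higher was 68.2%, and 87.7% with scaling to basal keratinocyte genes. The counts were 949 higher and 374 lower with normexp correction, and 2161 and 1361 with every gene kept regardless of signal.

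The late list had a median of −1.18 with calcium, with 27 of 48 genes at least 2-fold lower and 5 higher in −/− cells. All 7 Sprr2 genes were at least 2-fold lower (median 8.14-fold), led by Sprr2d (15.4-fold; chromosome 3, 92144721 to 92144780, mm9), Sprr2e (14.2-fold), Sprr2g (9.1-fold) and Sprr2k (8.14-fold), with the pseudogene Sprr2j-ps also among the 10 lowest genes. Of 18 Lce genes 15 were at least 2-fold lower (median 2.72-fold), including Lce3a (8.07-fold). Probes of such near-identical genes can share signal, so the families are better measured than their members. The envelope genes Lor (2.54-fold), Cnfn (2.25-fold) and Tgm1 (2.17-fold) were lower, while corneodesmosin (Cdsn, 2.06-fold) and Scel (3.33-fold) were higher. Late genes without Lce and Sprr had a median of −0.41. The early list had a median of −0.19, with Grhl3 2.49-fold lower and Dsg1a 10-fold higher, and did not stand apart. The desquamation (−0.10), barrier lipid (−0.02), tight junction (−0.26) and EGF ligand (0.05) lists did not stand apart either. Basal keratinocyte genes had a median of −0.45, with 18 of 20 below 0, and no longer stood apart (−0.36) with the mean of a gene's probes. Igfbp3 was 5.3-fold higher against that direction.

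Activation and hyperplasia genes had a median of −0.57 with calcium, and 11 of 38 were at least 2-fold lower in −/− cells. The alarmin Il36a, named Il1f6 on the array, was at least 40.9-fold lower, being not well above background in −/− cells. Csf3 was 8.48-fold, Il33 4.52-fold, Slpi 3.98-fold and S100a8 3.54-fold lower. The neutrophil chemokines Cxcl5 and Cxcl1 were 8.63-fold and 4.13-fold lower, whereas Ccl3 was 32.6-fold higher, and the chemokine list as a whole (median −0.32) did not stand apart. Ptx3 (8.68-fold), Rab6b and Slc6a14 were also among the 10 genes lower by the most. Krtap3-2 and Spink2 followed Il1f6 among the bounds. Heat shock genes had a median of −0.43, just outside the range of matched random lists (−0.41 to −0.12). Cell cycle genes, at −0.07, did not stand apart.

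**Figure D2:**
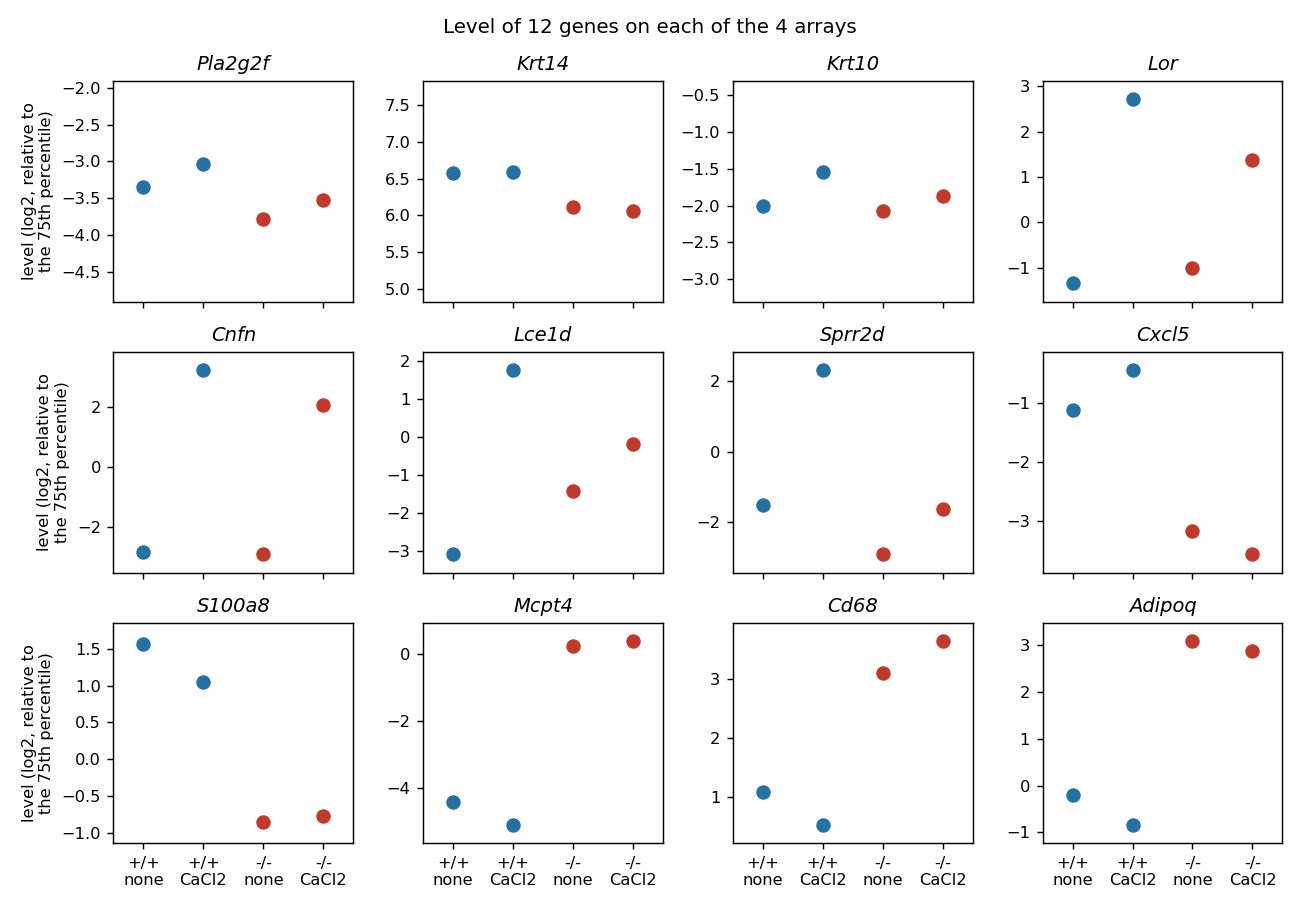
Level of 12 genes on each of the 4 arrays (log2 relative to the array's 75th percentile; blue +/+, red −/−; none or 1 mM CaCl2 added), 1 point per array, with a separate vertical range in each panel. Sprr2d is 15.4-fold and Cxcl5 8.63-fold lower in −/− than in +/+ cells with calcium, and Mcpt4 45.7-fold higher.

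On the high side with calcium were Reg1 (77.6-fold), Mcpt4 (45.7-fold), Cd5l (33.3-fold), Ccl3, Cpa3 (30.9-fold), Car3, Cyp2e1, Slco2b1, Cma1 (23.8-fold) and the macrophage mannose receptor Mrc1 (23.5-fold), with Cyth4 (at least 29.7-fold) and Ccl12 among the largest bounds. The mast cell list had a median of 3.77 (9 of 9 at least 2-fold higher), adipocyte markers 2.90 (8 of 9), myeloid markers 2.16 (8 of 13), erythroid markers 1.71 (3 of 6), fibroblast markers 1.31 (14 of 19) and skeletal muscle markers 1.00 (6 of 11). Among fibroblast markers Dlk1 was 9.46-fold and Col3a1 2.85-fold higher. Schwann cell (0.68), sebaceous (0.67) and pericyte (0.54) markers were higher as well. Endothelial (−0.47) and Merkel and simple epithelial (−0.81) markers were lower, and melanocyte (−0.17), T cell (−0.18) and hair follicle (−0.29) markers did not stand apart.

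Alongside these markers, fatty acid and PPAR target genes had a median of 0.84 with calcium (Cd36 6.31-fold, Pparg 5.77-fold higher), eicosanoid genes 0.54 (Alox5ap 11-fold, Ephx2 8.53-fold), interferon genes 0.52, NRF2 target genes 0.38, TGF-beta and mesenchymal genes 0.25, lysophospholipid genes 0.20 (Enpp2 8.41-fold), hypoxia and glycolysis genes 0.19 and unfolded protein response genes 0.04, each above matched random lists. The phospholipase A2 family as a list did not stand apart without calcium (−0.19) or with it (10 of 20 genes below 0). Within it Pla2g7, which inactivates platelet-activating factor, was 4.76-fold and 6.39-fold higher in −/− cells, the triglyceride lipase Pnpla2 3.87-fold and 3.14-fold, and the skin enzyme Pla2g2e 2.46-fold and 2.29-fold. Pla2g4d was at least 2.55-fold lower without and 3.92-fold lower with calcium.

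**Figure D3:**
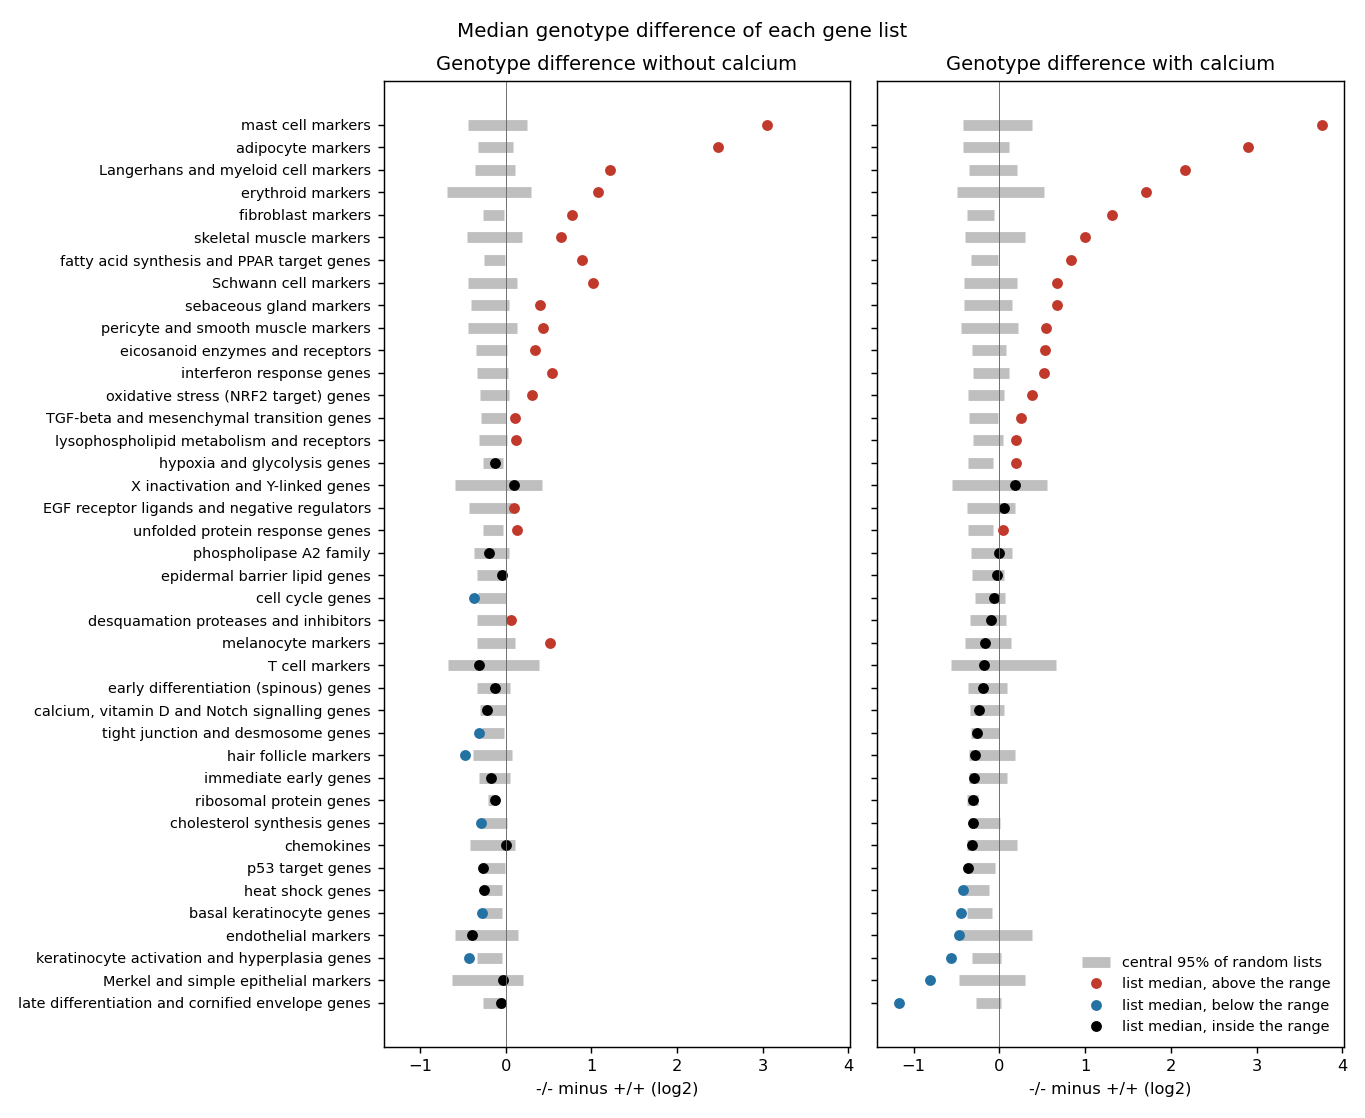
Median −/− minus +/+ difference (log2, horizontal axis) of the genes of each of 40 lists, without calcium on the left and with calcium on the right, 1 array per group. Grey bars span the central 95% of 10000 random lists matched on mean level; red points lie above (19 lists without and 17 with calcium), blue points below (6 and 6), and mast cell markers are farthest right at 3.04 and 3.77.

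The genotype differences without and with calcium came from separate arrays, though the same mice may stand behind both. They correlated across genes with Pearson r = 0.839 and Spearman rho = 0.731, and 94.6% of the 1993 genes at least 2-fold different in either had the same sign in both. At least 2-fold higher in both were 708 genes, against 45.7 for independent lists, 186 were lower in both, against 12.8, and 7 went opposite ways. Of 40 lists, 13 and 11 stood above and below matched random lists in the +/+ calcium response, 15 and 8 in the −/− response, 19 and 6 between genotypes without calcium, 17 and 6 with calcium and 11 and 9 in the response difference, where 2.0 would fall outside by chance. Genes of a list are coexpressed, which makes these percentiles too extreme.

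Genes around a targeted locus can carry alleles of the embryonic stem cell strain, so the neighbourhood of Pla2g2f was examined. Within 5 Mb the complement genes C1qa, C1qb and C1qc of macrophages, the muscle gene Trim63 and the deiminase Padi2 were higher in −/− cells, and the myelin gene Ncmap, Stmn1, Pdpn and Cep85 lower; these were picked after their values were seen. C1qa differed by 3.25 log2 without and 4.43 with calcium, and Ncmap by −2.38 and −2.25. The median absolute genotype difference of 185 genes was 0.42 without calcium, against 0.26 to 0.37 in matched random lists, and 0.41 for 186 genes with calcium, against 0.28 to 0.39. The signed median was −0.25 in both cultures. At least 2-fold higher were 10 and 13 of these genes, and lower 17 and 19.

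Several function lists differed little with calcium, while some cell type lists lay well outside the random range. In +/+ cells cholesterol synthesis (0.24), chemokine (0.18) and calcium, vitamin D and Notch signalling genes (0.11) stood above it, and eicosanoid (−0.30), fatty acid and PPAR (−0.28) and interferon genes (−0.23) below. Phospholipase A2 family (−0.05), lysophospholipid (−0.05), unfolded protein response (−0.05), NRF2 target (−0.11), p53 target (−0.07), TGF-beta (0.02), hypoxia and glycolysis (−0.05), heat shock (0.06), immediate early (0.07) and ribosomal protein genes (−0.05) did not stand apart. In −/− cells cholesterol synthesis (0.25), immediate early (0.14), hypoxia and glycolysis (0.04) and TGF-beta genes (0.03) stood above, and interferon (−0.28) and p53 target genes (−0.21) below. Merkel and simple epithelial markers had a median of 1.05 in +/+ and 0.25 in −/− cells, skeletal muscle markers 0.60 and 0.69, pericyte and smooth muscle markers 0.36 and 0.39, and mast cell markers −0.70 and −0.14. Below the random range were adipocyte markers in both (−0.58 and −0.33), erythroid (−0.76), myeloid (−0.55), sebaceous (−0.39) and fibroblast markers (−0.23) in +/+ cells, and T cell (−0.44), Schwann cell (−0.33) and melanocyte markers (−0.32) in −/− cells. Myeloid (0.17) and fibroblast markers (0.13) stood above it in −/− cells.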

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

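The tests of keratinocyte share, shared probe signal, added cells, dermal carry-over and cell type genes near the target were chosen only after the result was seen; those of scaling, of an ordinary window and of strain alleles were not.

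Among genes measured on all 4 arrays and at least 2-fold different in both genotypes, calcium responses went opposite ways for 2, and 2 marker lists stood apart in opposite directions. The chemokine Ccl3 was lower with calcium in +/+ cells (−1.65 log2) and higher in −/− cells (1.25), a difference of 2.90; with normexp correction the +/+ value was −0.92. The transcript 4930592A05Rik, named after its values were seen, had −1.14 and 1.31, a difference of 2.45. Fibroblast markers had medians of −0.23 and 0.13, a difference of 0.36, and Langerhans and myeloid markers −0.55 and 0.17, a difference of 0.73. Members of the myeloid list went both ways, with 6 above and 7 below 0 in +/+ cells and 9 above and 5 below in −/− cells. None of these differences was tested, and with 1 array per group no check for an outlying array was possible.

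With calcium, Lce and Sprr2 genes were lower in −/− cells. A lower share of keratinocytes in that culture predicts a like difference in early differentiation genes. Yet the Lce and Sprr2 median of 25 genes (−2.01) lay −1.82 log2 from that of 19 early genes (−0.19). The bootstrap 95% interval over genes was −2.10 to −1.20. It resamples coexpressed genes of single arrays, which are no replicates, and holds no spread between cultures or arrays. One signal shared by near-identical probes stays open, since medians of −1 or lower in 3 of 3 families (Sprr2, Lce1 and Lce3) would also follow from sharing within each family. Late genes outside Lce and Sprr had calcium responses of 1.84 in +/+ and 2.21 in −/− cells at the median. These medians include lower bounds and genes not induced in +/+ cells, such as Tgm3 (−0.16) and Padi1 (−0.07). The response difference was available for 17 late genes outside Lce and Sprr. It was below 0 for 7, with 5 at least 2-fold below and 1 at least 2-fold above 0. The medians therefore cannot decide whether induced late genes as a group responded less. A weaker induction of the Lce and Sprr2 families in −/− cells may explain the pattern, but this cannot be separated from a difference between the cell preparations of the genotypes.

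Mast cell, myeloid and adipocyte markers were higher in −/− cells in both cultures. Background or scaling is argued against by the lowest median of these lists over all such settings, 0.98 log2. The mast cell median exceeded the endothelial one by 4.24 with calcium (bootstrap 95% interval over genes 1.93 to 5.30). The interval resamples 9 and 9 coexpressed genes of single arrays and holds no spread between cultures. This comparison cannot decide on carry-over of whole dermis, since carried-over cells need not persist alike through 3 days of culture and 48 h of treatment. Carry-over of dermis, whole or in part, stays open. Fibroblast (1.31), skeletal muscle (1.00), Schwann cell (0.68) and vessel-related pericyte markers (0.54) were also higher with calcium. The erythroid median was higher too (1.71), with 3 of 6 genes at least 2-fold higher. More mast cells, myeloid cells and adipocytes in the −/− cultures is a candidate explanation that cannot be told apart from changed expression or from the cell preparation: that 77.4% of measured members (24 of 31) were at least 2-fold higher in both cultures restates the pattern, with abundant markers at these levels with calcium in +/+ and −/− cells: Fabp4 4.46 and 6.02, Cd68 0.51 and 3.64, and Tpsb2 0.03 and 1.66. In +/+ cultures 8 of 9 mast cell, 13 of 14 myeloid and 9 of 9 adipocyte markers were well above background, and 1, 0 and 3 stand in other lists.

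Genes within 5 Mb of Pla2g2f differed more between genotypes than matched random genes. Genes of added cells lying there cannot be told apart as a reason: the signed median was at percentile 1.23, but over genes that go both ways, and C1qa, C1qb and C1qc are macrophage genes. An ordinary stretch of the genome is a candidate explanation, since 7.85% of 1733 other windows had a median absolute difference as large with calcium. That is the higher share of the 2 cultures. These windows of 10 Mb were moved in steps of 1 Mb, so they overlap and are not independent. Alleles of an embryonic stem cell strain cannot be told apart from it. Genes within 2 Mb differed by 0.0765 more than those at 5 to 20 Mb with calcium, the culture with the smaller excess. The bootstrap 95% interval over genes was −0.03 to 0.14.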

How the results depend on the processing

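Scaling to basal keratinocyte genes was chosen after seeing the data, and only that setting. No paired analysis was possible because the groups compared share 1 replicate number and the results come from no test; an additive fit of genotype and treatment over the 4 arrays was not used. Counts of genes are given as higher and lower (response difference: above and below 0). Of 103 counts and sizes under the alternatives 61 were within their tolerance (1.5-fold for counts) and 42 were not. Correlations and response sizes moved by less than 0.1.

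Normexp correction gave 328 and 62 in the +/+ calcium response, 319 and 26 in the −/− response, 655 and 188 between genotypes without calcium, 374 lower with calcium, and 115 and 67 in the response difference. Quantile scaling gave 399 lower without calcium and 187 and 184 in the response difference. The cause was not tested for either. Scaling to basal genes gave 895 and 86, 1352 and 45, 1511 and 337, and 2216 and 310 in the calcium responses of +/+ and −/− cells and the genotype differences without and with calcium. It moved the all-gene medians to 0.25, 0.31, 0.11 and 0.15, because the basal list was lower in all 4 comparisons.

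Keeping only genes well above background on both arrays left 128 and 59 lower in the +/+ and −/− responses and 525 lower without calcium, since bounds were dropped. With no filter there were 886 and 1097, 1919 and 447, 2982 lower without calcium, 2161 and 1361 with calcium, and 3098 and 746 in the response difference, since dim genes were added. A 3-fold threshold, stricter by construction, gave 239 and 46, 251 and 24, 461 and 158, 717 and 176, and 47 and 40 in the order of comparisons above, the response difference last.

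Of 152 medians of the main lists 147 stayed on their side of the random range. Basal genes no longer stood apart without calcium under quantile scaling (−0.17) or the mean of probes (−0.28), nor with calcium under the mean of probes (−0.36). Late genes stood apart without calcium under quantile scaling (0.0795), and activation genes in the response difference under the mean of probes (−0.10). The cause was not tested. Of 1368 medians of other lists 1332 were on the same side, 19 newly stood apart and 17 no longer did. Of 768 values of named genes 591 stayed within tolerance, 177 moved and 0 reversed. Normexp correction moved 92 of these and kept 36, and scaling to basal genes moved 77 and kept 51. The authors' value table and scaling to the median of probes well above background shift all genes of an array alike. Counting near-identical families once changes only lists that hold them. Agreement under these settings was therefore close to given, and the pooled counts include it. Signal over background limits the dim genes, whose differences are bounds.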

Other observations

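The test of the epidermal differentiation complex was chosen only after the result was seen.

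Several single members of the eicosanoid and barrier lipid lists differed by more than their list medians. The prostaglandin D2 synthases Hpgds and Ptgds were 4.27-fold and 3.63-fold higher in −/− cells without calcium, while Ptgds was 2.33-fold and 3.53-fold lower with calcium than without in +/+ and −/− cells. Thromboxane synthase (Tbxas1) was at least 6.17-fold and at least 16.2-fold higher in −/− cells without and with calcium. In these −/− libraries mast cell markers had median genotype differences of 3.04 and 3.77, and myeloid markers 1.22 and 2.16. A change within keratinocytes therefore cannot be told apart from a share of other cells. The lipoxygenase Aloxe3, which acts on ceramides of the barrier, was 3.59-fold lower in −/− cells with calcium. Hpgd, which inactivates prostaglandins, was 4.48-fold and 3.82-fold higher with calcium in +/+ and −/− cells.

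The Notch target Nrarp was 3.88-fold higher with calcium in +/+ cells and 9.99-fold in −/− cells, and the upper follicle keratin Krt79 2.67-fold and 9.02-fold. These differences between genotypes were not tested.

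Lce and Sprr genes lie in the epidermal differentiation complex, a gene cluster on chromosome 3 (90314959 to 93368437, mm9) with 76 measured genes. The calcium-induced genes of the whole cluster, not these families alone, may respond less to calcium in −/− cells. Its 10 calcium-induced genes outside those families were all smaller in −/− cells, with a median response difference of −1.43. Calcium-induced genes elsewhere had −0.05, with 162 of 300 smaller, so the 10 cluster genes lay −1.38 log2 from them. The bootstrap 95% interval over genes was −1.92 to −0.81 and holds no spread between cultures or arrays. The 25 Lce and Sprr genes had a median of −2.54, with 24 smaller. Families were told apart by symbol alone. The 10 include the clone or transcript names 2210017I01Rik, 2310046K23Rik, 2310050C09Rik and ENSMUST00000050758, whose family was not checked. The cluster also holds genes outside this selection with a response difference above 0, such as S100a8 (0.60) and Ivl (0.49). The genotype and the cell preparation stay open as reasons.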
